A study of Mus musculus with 6 samples.

How the data were processed

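The 6 samples of C2C12 cells, 3 labelled as control myoblasts and 3 as differentiated for 7 days, were assayed. RNA was isolated with Trizol, treated with DNase and purified on RNeasy columns, per the labels' protocols. Expression of 72 H/ACA snoRNAs was read with a custom NanoString nCounter panel, per the series' design text.

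The deposited table held a normalized signal, a probe count multiplied by one factor per sample. The unit and the factor were inferred from the values. In every sample all 67 measured values were whole multiples of one step, within a tolerance of 0.05 of a count. The steps were 1.3069, 1.009 and 1.0827 in myoblast samples 1 to 3 and 1.1138, 1.0766 and 1.0695 in myotube samples 1 to 3. What the factor was derived from, and whether a background was removed, is not given in the sources used here. The table held no reference, spike-in or negative control probes, so neither the scaling nor a detection limit could be checked, and scaling on reference probes was not run. Dividing by the step gave implied totals of 1097844, 1570369 and 1467770 counts in the myoblast samples and 1573930, 1627062 and 1583107 in the myotube samples. Over probes, the counting error of a log2 difference between samples had a median between 0.0187 and 0.0217 over pairs of samples, far below the spread between replicates. It covers counting error only.

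Probes were named by matching RefSeq accessions, without versions, to an annotation of the mouse assembly GRCm38.p6, which gave symbols for 34 of 72 probes, 33 of them with values. The other 38 carry Ensembl transcript identifiers that the annotation does not pair with symbols. Host genes are those whose annotated span contains the snoRNA in that annotation, and 1 of them is not reported here. The genome build behind the probes is not given in the sources used here, so no coordinates are printed. Probes may also bind near-identical copies of a snoRNA elsewhere in the genome, such as Snora73b for Snora73a, and values of such families are uncertain to that extent.

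Values were analysed as log2(value + 1), so fold changes are on that scale. The model was limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend) with state as the only term, two-sided, and Benjamini-Hochberg adjustment over the 67 measured snoRNAs with a threshold of 0.05. Positive changes are higher in myotubes. Lists were tested with limma's fry, which asks whether a list's members move one way on balance, and camera, which sets a list against the other snoRNAs. Both were adjusted over the 5 lists with measured members. Single values were compared with exact permutation tests over the splits of the 6 samples, where the smallest p is 0.1. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the remaining steps.

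Before the data were examined, 6 lists were fixed from background knowledge of human orthologues. They were 18S rRNA guides, 28S rRNA guides, snoRNAs of pre-ribosomal RNA cleavage, snoRNAs in translation gene hosts, snoRNAs in non-coding hosts, and those of the host gene Taf1d. No member of the Taf1d list was measured under a symbol, so it gave no result, and members present only as transcript identifiers were not counted in any list. The named snoRNAs were also fixed by rule. They are the 10 largest rises and 10 largest falls among calls without overlap between groups, the 3 highest means, the 3 smallest changes among snoRNAs above the panel's median abundance, and the members of the pre-ribosomal RNA list. Telomerase RNA, small Cajal body RNAs and markers of muscle, proliferation or fibroblasts were to be named if present, and none was found under a symbol. At most 2 transcript identifiers are printed in each direction, since these probes have no symbol here. Every other called snoRNA with a symbol is named too, which was decided after the values were seen, as were the mentions of Snora23, Snora35, Snora69, Snora75, Snora81 and the pairs sharing a host gene. Levels of different probes also reflect how well each probe hybridises.

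For this comparison 50 panels of 67 probes were simulated, with 30 changed probes each. Residual spread was drawn from the variance distribution that limma estimated. Changes of 1.41-fold, 2-fold and 4-fold were called in 58.6%, 93.2% and 99% of cases, and 3.32% of calls were false. The simulated errors were independent between probes and even between samples. In the data the samples were unevenly spaced and members of some lists were correlated, so these rates may not hold for the data. Alternatives were subtraction of sample medians, quantile normalization, equal panel totals, pseudocounts of 10 and 0.1, leaving out snoRNAs with a mean under 20, keeping the 50 snoRNAs with the highest means, the replicate number as a block, a robust fit with trend, an added 1.5-fold threshold, and leaving out each sample. Averaging myotube samples 1 and 2 was added after seeing the data. Count models were not used, because the table holds scaled values.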

Results

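Box H/ACA small nucleolar RNAs (snoRNAs) guide the conversion of uridine to pseudouridine in ribosomal RNA, and a few of them act in the cleavage of its precursor. Their levels were measured in C2C12 cells, a mouse myoblast line that fuses into multinucleated myotubes on differentiation. Total RNA from 3 samples of undifferentiated myoblasts and 3 samples of cells differentiated into myotubes for 7 days was hybridised to a custom NanoString nCounter panel, which counts colour-coded probes without amplification. The panel held 72 snoRNA probes, of which 67 had values in all 6 samples and 5 had none in any sample. The probe of Snora35, which lies in the serotonin receptor gene Htr2c, was among those with no value. Symbols were available for 33 of the measured probes, and 34 were known only by a transcript identifier. The count implied by the step of the values, summed over the panel, ranged from 1097844 in myoblast sample 1 to 1627062 in myotube sample 2. The sources do not say whether the samples of a group came from separate cultures, so p-values measure the spread between these samples only, which may be technical.

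The panel spanned a wide range of abundance in both states. Snora73a (U17), which takes part in pre-ribosomal RNA cleavage, had the highest level in myoblasts, with a normalized count of 208063 ± 7947 (SD, n = 3). A probe without a symbol, ENSMUST00000082448, stood at 164029 ± 6467 in myoblasts and 167297 ± 19555 in myotubes (SD, n = 3 each). Snora16a, in the long non-coding host gene Snhg12, had the third highest mean over all samples, at 87696 ± 12771 in myoblasts and 98619 ± 632 in myotubes (SD, n = 3 each). These 3 snoRNAs, the highest by mean over all samples, took between 22.7% and 30.2% of the summed normalized count of a sample. At the other end, Snora23, in the importin gene Ipo7, was measured at 63.4 ± 6.2 in myoblasts and 64.6 ± 10.2 in myotubes (SD, n = 3 each). Its implied counts were between 46 and 70, the lowest of the panel. Without negative control probes, a low level of Snora23 could not be told from background.

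Myotubes were compared with myoblasts to ask which snoRNAs are regulated during differentiation. Of the 67 snoRNAs tested, 37 differed between the states, 24 higher in myotubes and 13 lower (limma, Benjamini-Hochberg adjusted p at or below 0.028). Among those with symbols, the largest rises were those of Snora36b, Snora30 and Snora28, with fitted folds of 3.66, 3.37 and 3.01. Snora52 and Snora43 showed the largest falls among those with symbols that passed the test, each 1.6-fold. A change of at least 2-fold was reached by 7 of the snoRNAs that rose and 6 of those that fell, and log2 changes over all snoRNAs ran from -2.09 to 1.87. The values of the groups did not overlap for any of the 37. Non-overlap held for 44 of all 67 snoRNAs, or 65.7%. Chance gives 10% for a single snoRNA. All 67 were read in the same 6 samples and are not independent, so this share is no test against chance. The remaining 30 snoRNAs did not pass the test, and for 23 of them the 95% interval of the change excluded 2-fold in either direction.

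The balance between rises and falls depended on the scale. The summed normalized count of the panel was 1536111 ± 87790 in myoblasts and 1732635 ± 34246 in myotubes (SD, n = 3 each), a ratio of 1.13, with an exact two-sided permutation p of 0.1, the smallest that 3 samples against 3 allow. Setting all samples to the same panel total moved the log2 changes by a median of -0.18 and gave 22 snoRNAs higher and 20 lower, with 35 of the calls among the 37. Quantile normalization moved them by the same median and gave 20 higher and 17 lower, of which 28 were among the 37, in the same direction. The median log2 change of the panel was 0.14 on the deposited scale (exact two-sided permutation p = 0.3).

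Snora36b, an 18S rRNA guide in an intron of Rab3gap2, rose 3.66-fold, from 674 ± 37.9 to 2480 ± 310 normalized counts (SD, n = 3 each; log2 change 1.87 ± 0.13 SE, adjusted p = 6.9e-05). Snora30, a 28S rRNA guide within the chromatin remodeller gene Srcap, rose 3.37-fold to 16640 ± 667 (SD, n = 3; log2 change 1.75 ± 0.18 SE, adjusted p = 0.0002). Snora28, an 18S rRNA guide in the translation initiation factor gene Eif5, rose 3.01-fold, from 35954 ± 7940 to 106309 ± 7284 (SD, n = 3 each; adjusted p = 0.00039). Snora47, in Zbed3, rose 2.28-fold (log2 change 1.19 ± 0.20 SE, adjusted p = 0.002). Snora74a (U19), a 28S rRNA guide in the non-coding host gene Snhg4, rose 1.99-fold, from 51256 ± 10141 to 100977 ± 7602 (SD, n = 3 each; adjusted p = 0.002). Under quantile normalization the log2 change of Snora74a went from 1.00 to 0.50 (adjusted p = 0.01). These are 5 of the 10 largest rises. The other 5 belonged to probes without a symbol, led by ENSMUST00000083184 at 2.84-fold and ENSMUST00000104066 at 2.59-fold.

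The 8 further snoRNAs with symbols that rose were named after their values were seen. Snora3, Snora70, Snora31 and Snora7a lie in Rpl27a, Rpl10, Tpt1 and Rpl32, of which all but Tpt1 encode ribosomal proteins. They rose by 1.92-fold, 1.79-fold, 1.69-fold and 1.52-fold in that order, with adjusted p between 0.0021 and 0.0073. Snora68, a 28S rRNA guide, rose 1.86-fold (adjusted p = 0.00039). Snora5c, in Tbrg4, rose 1.69-fold (adjusted p = 0.0011) and Snora15, in the chaperonin gene Cct6a, 1.56-fold (adjusted p = 0.028). Snora17, in Snhg7, rose 1.36-fold (adjusted p = 0.024). The calls of Snora15 and Snora17 were lost without myotube sample 1 or 2, at adjusted p of 0.081 to 0.085, and with these samples averaged, at 0.081 each. Quantile normalization also ended the calls of Snora15, Snora17 and Snora31 (adjusted p of 0.18, 0.084 and 0.058). Their log2 changes were 0.37, 0.32 and 0.44 there, against 0.64, 0.45 and 0.76. Subtraction of sample medians ended that of Snora17 (adjusted p = 0.081), as did the replicate number as a block (adjusted p = 0.08). In both of these fits the adjusted p followed the size of the change alone. Quantile normalization took the log2 changes of Snora70 from 0.84 to 0.33, of Snora68 from 0.90 to 0.52 and of Snora7a from 0.60 to 0.37 (adjusted p of 0.046, 0.021 and 0.039). Without myoblast sample 1 that of Snora15 went from 0.64 to 0.42, and with equal panel totals that of Snora17 from 0.45 to 0.27.

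**Figure D1:**
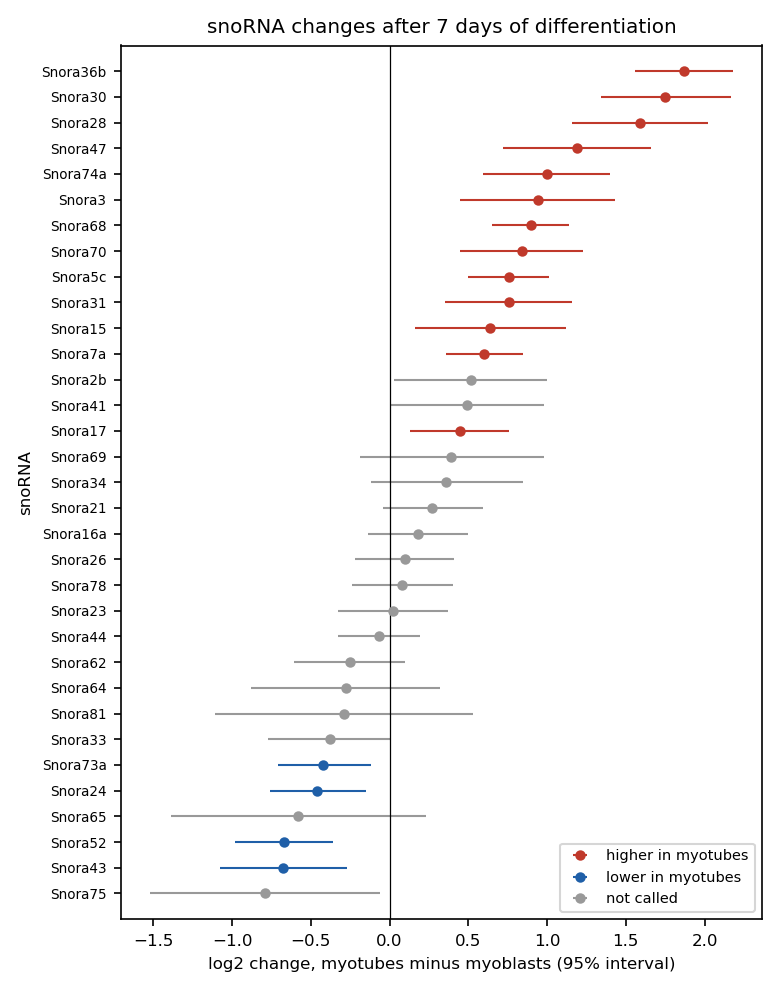
Log2 change from myoblasts to myotubes of the 33 measured snoRNAs with a symbol. Points are limma estimates from 3 samples per state and bars are 95% intervals; 13 snoRNAs were called higher, 4 lower, and the estimates run from -0.79 for Snora75 to 1.87 for Snora36b.

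Of the 13 snoRNAs that fell, 4 had symbols. Snora43, a 28S rRNA guide in Snhg7, fell from 6310 ± 1233 to 3899 ± 330 normalized counts (SD, n = 3 each), 1.6-fold (adjusted p = 0.012). Snora52, a 28S rRNA guide in the ribosomal protein gene Rplp2, fell from 22851 ± 2937 to 14247 ± 423 (SD, n = 3 each), also 1.6-fold (adjusted p = 0.0037). Snora24, an 18S rRNA guide in Snhg8, fell 1.37-fold (adjusted p = 0.019) and was named after its values were seen. Snora73a fell 1.34-fold to 156495 ± 18794 (SD, n = 3; adjusted p = 0.024). Among the 10 largest falls, 8 were of probes without a symbol. ENSMUST00000083331 showed the largest change of the panel, 4.25-fold lower at 1163 ± 174 against 4930 ± 623 (SD, n = 3 each; adjusted p = 6.9e-05), and ENSMUST00000104426 was 2.62-fold lower. The calls of Snora24 and Snora73a ended when any of myoblast samples 2 and 3 or myotube samples 1 and 2 was left out (adjusted p between 0.063 and 0.11). They also ended with myotube samples 1 and 2 averaged, at 0.071 and 0.11, and with the replicate number as a block, at 0.077 and 0.11. Under quantile normalization their log2 changes went from -0.46 to -0.81 and from -0.42 to -0.22. That of Snora43 ended without myoblast sample 3 (adjusted p = 0.054) and under quantile normalization (adjusted p = 0.089).

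**Figure D2:**
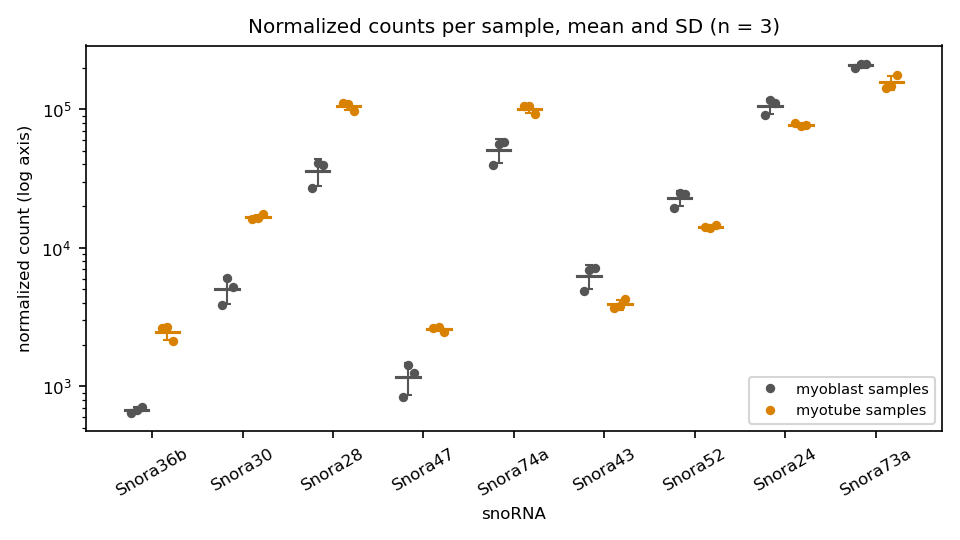
Normalized counts of the 5 snoRNAs with symbols among the largest rises (left) and of the 4 with symbols that fell (right), on a log axis. Points are samples, horizontal lines are means and bars are SD (n = 3 per state); in each of these snoRNAs the 3 myotube samples lie entirely above or entirely below the 3 myoblast samples.

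Neighbouring snoRNAs of one host gene did not always move together. Snora17 and Snora43 both lie in Snhg7, yet Snora17 rose and Snora43 fell. The log2 ratio of Snora17 to Snora43 was 2.3 ± 0.10 in myoblasts and 3.42 ± 0.12 in myotubes (SD, n = 3 each), a difference of 1.13 with an exact two-sided permutation p of 0.1, the smallest possible. For Snora16a and Snora44, both in Snhg12, the log2 ratio differed by 0.25 ± 0.08 SE (exact permutation p = 0.1), and neither snoRNA passed the test alone. Snora44 was among the 3 smallest changes of abundant snoRNAs, at a log2 change of -0.07 ± 0.11 SE, and passed the test with equal panel totals (-0.24, adjusted p = 0.039) but not under quantile normalization (-0.31, adjusted p = 0.061). Both others of these 3 had no symbol, with log2 changes of 0.02 for ENSMUST00000082448 and -0.04. Under quantile normalization ENSMUST00000082448 and Snora73a gave 0.22 and -0.22 (limma, adjusted p = 0.0021 each). These probes hold the top ranks and swap them between the states. The pass of ENSMUST00000082448 is thus the mirror image of the fall of Snora73a. The ratios of Snora2b to Snora34 in Kansl2 and of Snora64 to Snora78, both within Rps2 and the latter also within Snhg9, differed by 0.16 ± 0.20 and -0.37 ± 0.43 (SE), with exact permutation p of 0.4 and 0.5.

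Guides of the small and of the large ribosomal subunit were set side by side because pseudouridylation of ribosomal RNA is the subject of the study. Of 8 listed 18S rRNA guides measured under a symbol, 5 rose (Snora36b, Snora28, Snora70, Snora5c and Snora15) and 1 fell (Snora24). Snora69 and Snora44 did not pass the test. Members were placed on both lists from background knowledge, and their targets were not checked here. Only snoRNAs with a symbol could be counted in the lists. Of all measured snoRNAs with symbols 13 rose and 4 fell, against 11 and 9 of those without. The place of Snora69 among guides of the small subunit is uncertain, and the list results below include it. The log2 change of Snora69 was 0.39 (adjusted p = 0.2), and ranged from 0.22 with equal panel totals (adjusted p = 0.46) and 0.23 without myotube sample 2 (adjusted p = 0.47) to 0.67 without myotube sample 3, where it passed (adjusted p = 0.0087). The median log2 change of the list was 0.70, and on balance the list moved up (fry, adjusted p = 0.021). It did not stand apart from the other snoRNAs (camera, adjusted p = 0.43; adjusted p = 0.79 with an estimated correlation). Under quantile normalization the median stayed above 0, at 0.35, but fry turned downward (adjusted p = 0.00085). Snora24 held one rank within each state, so this normalization left it no spread (log2 change -0.81, limma, adjusted p = 2.6e-05). How far this single member turned the test was not examined, so the turn is not read as a fall of the list. Of 17 measured 28S rRNA guides, 5 rose (Snora30, Snora74a, Snora68, Snora7a and Snora17), 2 fell (Snora52 and Snora43) and 10 did not pass. Their median was 0.18 and the directional test missed the threshold (fry, adjusted p = 0.062). Counts adjusted over the list alone were identical to those over all snoRNAs for both lists. The difference between the medians of the lists was 0.52, with an exact two-sided permutation p of 0.1, the smallest the design allows. The call for the 18S rRNA guides was lost whenever myoblast sample 2 or 3 or myotube sample 1 or 2 was left out, at adjusted p of 0.065 to 0.1, and with these myotube samples averaged (adjusted p = 0.1). For the 28S rRNA guides the median was 0.12 with sample medians subtracted (adjusted p = 0.11), 0.01 with equal panel totals (adjusted p = 0.16) and 0.00 under quantile normalization, where the test passed upward (adjusted p = 0.0095). It also passed without myoblast sample 1, at a median of 0.05 (adjusted p = 0.016), and without myotube sample 3, at 0.18 (adjusted p = 0.006), and missed without any of the other samples (adjusted p of 0.11 to 0.21).

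Of the snoRNAs tied to pre-ribosomal RNA cleavage, Snora73a (U17) and Snora62 (E2) were measured under a symbol. Snora73a fell and Snora62, in the ribosomal protein gene Rpsa, had a log2 change of -0.25 ± 0.15 SE (adjusted p = 0.19). Snora62 passed the test with equal panel totals (-0.43, adjusted p = 0.015), under quantile normalization (-0.42, adjusted p = 0.049) and without myoblast sample 1 (-0.39, adjusted p = 0.014), and was weakest without myoblast sample 3 (-0.17, adjusted p = 0.44). The pair moved down on balance (fry, adjusted p = 0.04), and did not stand apart from the other snoRNAs (camera, adjusted p = 0.43; adjusted p = 0.79 with an estimated correlation). Adjusted over the list alone the count was the same, 1 lower and none higher. This call was lost without myoblast sample 2 or 3 or myotube sample 1 or 2 (adjusted p between 0.11 and 0.14), with myotube samples 1 and 2 averaged (adjusted p = 0.14) and with sample medians subtracted (adjusted p = 0.076).

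By host gene, 6 of 15 measured snoRNAs in introns of ribosomal protein and other translation genes rose, 1 fell and 8 did not pass. Snora28, Snora3, Snora70, Snora31 and Snora7a were among the rises and Snora52 was the fall. Their median log2 change was 0.39 (fry, adjusted p = 0.069). It was 0.22 with equal panel totals (adjusted p = 0.18), 0.23 without myotube sample 2 (adjusted p = 0.21) and 0.25 with myotube samples 1 and 2 averaged (adjusted p = 0.21). The test passed under quantile normalization, at 0.26 (adjusted p = 0.028), without myoblast sample 1, at 0.46 (adjusted p = 0.035), and without myotube sample 3, at 0.57 (adjusted p = 0.006). In myotube sample 3 these snoRNAs stood at a median of -0.44 (log2) from the mean of myotube samples 1 and 2. Several of the members that did not pass varied widely between samples of one state. Snora81, in the initiation factor gene Eif4a2, ranged from 24645 to 53081 in myoblasts and from 18384 to 36540 in myotubes. Of 8 measured snoRNAs on the list of long non-coding host genes, 2 rose (Snora74a and Snora17), 3 fell (Snora43, Snora24 and Snora73a) and 3 did not pass. Their median and mean log2 changes were both 0.01, while the directional test leaned downward (fry, adjusted p = 0.94). Fry's test for change in either direction passed (adjusted p = 5.2e-05). It also passed for the translation hosts and 28S rRNA guides (adjusted p = 5.2e-05 each) and the 18S rRNA guides (0.00017), but not for the pre-ribosomal RNA list (0.31). For the non-coding hosts the median was below 0 with sample medians subtracted (-0.05), with equal panel totals (-0.17) and under quantile normalization (-0.11). Under quantile normalization the downward test passed (fry, adjusted p = 0.002). Snora24 and Snora73a, both lower in myotubes and without spread there, are on the list. For both host lists the counts adjusted over the list alone were the same. No list stood apart from the other snoRNAs (camera, adjusted p of 0.43 or above; 0.79 with an estimated correlation).

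The replicates were unevenly spaced. The SD over snoRNAs of the log2 difference between myotube samples 1 and 2 was 0.081, against 0.353 and 0.371 between each of them and myotube sample 3. In myoblasts it was 0.21 between samples 2 and 3, and 0.492 and 0.359 between sample 1 and these. The implied counts of myotube samples 1 and 2 still differed by more than counting noise (chi-square of 881.6 on 66 degrees of freedom), so they are not one set of counts deposited under both names. They were counted as labelled, as 2 samples, although repeat measurements of one RNA extract would also differ by more than counting noise. Counted as 1 averaged sample, they left 31 snoRNAs called, 20 higher and 11 lower, of which 30 were among the 37.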

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

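The count of 37 changed snoRNAs stayed between 27 and 42 over all alternatives. Apart from the added 1.5-fold threshold, which kept 30, 25 of them were called in every alternative that tested them, 17 higher and 8 lower. The filter at a mean of 20 removed no snoRNA. Equal panel totals raised the number lower in myotubes to 20 and moved the median log2 change to -0.04. Under quantile normalization the median was 0.03, the gap between 18S and 28S rRNA guides 0.35, the 18S rRNA guides 0.35 with fry reversed to downward (adjusted p = 0.00085), the 28S rRNA guides 0.00 (test upward, adjusted p = 0.0095), the translation hosts 0.26 (adjusted p = 0.028) and the non-coding hosts -0.11 (adjusted p = 0.002). With sample medians subtracted the pre-ribosomal RNA list stood at -0.39 (adjusted p = 0.076). With the 50 snoRNAs of highest mean alone the subunit gap was 0.37, the 28S rRNA guides 0.27 (adjusted p = 0.027) and the translation hosts 0.39 (adjusted p = 0.036). The cause of these shifts was not tested. Leaving out each sample gave medians of 0.05 to 0.17 for the panel, 0.49 to 0.58 for the subunit gap, 0.57 to 0.76 for 18S rRNA guides, 0.05 to 0.25 for 28S rRNA guides, -0.42 to -0.28 for the pre-ribosomal RNA list, 0.23 to 0.57 for translation hosts and -0.07 to 0.06 for non-coding hosts, which passed, downward, only without myoblast sample 1 (adjusted p = 0.019). With myotube samples 1 and 2 averaged, the 18S rRNA guides (0.67, adjusted p = 0.1) and the pre-ribosomal RNA list (-0.33, adjusted p = 0.14) lost their calls. Whether shared replicate numbers pair the samples is not given in the labels. Deviations from the group means correlated at 0.44, -0.74 and -0.02, and none of the 3 myoblast samples correlated best with its own number. With 3 samples per group this cannot settle the pairing. With the replicate number as a block, 38 snoRNAs were called, 32 of them shared, and the 18S rRNA guides (0.70) and pre-ribosomal RNA list (-0.34) both missed the threshold at adjusted p = 0.11. For the individual snoRNAs with symbols or picked by rule, 26 comparisons lost a call, 23 gained one and 708 stayed on the same side. The last count includes the filter at a mean of 20 and the pseudocounts of 10 and 0.1. These left the 37 calls unchanged, so it overstates the stability. Depth was lowest for Snora23, with 46 to 70 implied counts. Scaling on reference probes was not run, as the table used here has none.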

Other observations

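All tests in this part were chosen after the values were seen, except the count over other splits of the samples. Outside the host lists above were 9 measured snoRNAs in protein-coding hosts outside translation, such as Snora36b in Rab3gap2, Snora30 in Srcap and Snora47 in Zbed3. They held 5 rises and no fall, with a median log2 change of 0.64. Of these rises, Snora36b, Snora30, Snora5c and Snora15 were already counted among the rRNA guides. In the other host classes 8 of 24 rose, and no difference between the shares was detected (two-sided Fisher's exact test, p = 0.43). Snora75, in the nucleolin gene Ncl, was the member with the lowest value, at a log2 change of -0.79 ± 0.31 SE (adjusted p = 0.064). It passed the test with equal panel totals (-0.97, adjusted p = 0.042) and without myoblast sample 2 (-1.03, adjusted p = 0.021). It passed too without myotube sample 2 (-1.03, adjusted p = 0.022) and with myotube samples 1 and 2 averaged (-0.92, adjusted p = 0.05). Further passes came with sample medians subtracted (-0.85, adjusted p = 0.00012) and with the replicate number as a block (-0.79, adjusted p = 0.0017). In the fits with medians subtracted or with the block, the adjusted p followed the size of the change alone. The spread of Snora75 itself did not count there. The change was smaller without myotube sample 3 (-0.52, adjusted p = 0.17) and without myoblast sample 1 (-0.56, adjusted p = 0.23). The normalized count ranged from 7098 to 13435 in myoblasts.

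The real split of the 6 samples called 37 snoRNAs and the highest of the other splits called 0, so 1 of the 10 splits gave as many. The 10 splits are too few for a share under 0.05. Every other split also mixes the states, so the difference between states enters the spread within its groups and lowers its calls. The count of 0 therefore says little about chance.

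One pattern is the opposite movement of Snora17 and Snora43 inside Snhg7. Their log2 ratio rose by 1.13 ± 0.09 SE and did so in 3 of 3 myotube samples. That argues against the amount of the shared host transcript as the only cause. The shift was 59.5 times its counting SD, which counts for little. Snora64 and Snora78 also differed far beyond counting error (-0.37, counting SD 0.028), without a detected difference (exact permutation p = 0.5). The scaling factor cancels in the ratio. A difference in processing or stability between these snoRNAs after transcription may be involved, and binding of either probe to another RNA stays open, as neither was tested.

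Within the groups, the list of snoRNAs in translation gene hosts was set beside the 18 other named snoRNAs. In myotube sample 3 the list stood at a median of -0.44 (log2) from the mean of samples 1 and 2, with 12 of 15 below 0, and the others at -0.08, with 11 below 0. In myoblast sample 1 the list stood at 0.04 from the mean of samples 2 and 3, with 7 below 0, and the others at -0.34, with 17 below 0. Each is a value of a single sample, with no replicate check.

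Another pattern is the closeness of myotube samples 1 and 2. A chi-square of 13.4 per degree of freedom argues against a single library deposited under both names. Whether they are repeat measurements of one RNA extract cannot be told apart from separate samples that were alike: the SD of their log2 differences was 0.081, and no technical repeat is labelled. If they were, the spread in myotubes could be underestimated, and 31 snoRNAs are called when the samples are averaged.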
